A study of Mus musculus with 24 samples.

How the data were processed

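Total RNA from 24 cultures of mouse retinal endothelial cell lines was measured on Affymetrix mouse arrays with a single biotin label. The deposited values are log2 probe set intensities that the submitters made with RMA (background correction, quantile normalization and summary of the probes), per the submitters' processing notes, which give no version. Those notes do not say which arrays were normalized together. The value distributions fall into 3 sets. The 12 arrays of cells grown alone have medians of 5.02 to 5.11, the 6 wild type co-cultures 3.44 to 3.52, and the 6 Fz4-/- co-cultures 3.21 to 3.31. A spike-in control for the 5' end of dap read 7.71 to 8.26, 5.43 to 8.03 and 2.60 to 3.01 in these sets. Genotype and array set therefore coincide in the co-cultures, and no model could part them. Whether the sets were normalized apart is not known.

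Of 45101 probe sets, 64 controls were left out, and 34945 with a single gene symbol in the platform's annotation were kept. Another 932 with several symbols and 9160 without a symbol were examined only as a group. A gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes. RefSeq gene annotation on assembly GRCm38.p6 held 34741 of the named probe sets by gene ID and was used only for gene names and for which genes are neighbours.

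Differences were fitted with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8). A linear model with a mean for each group was fitted apart for the 12 single cultures and the 12 co-cultures, which leaves 8 residual degrees of freedom per fit, followed by empirical Bayes moderation of the variance. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes of a comparison are called past the threshold. Errors beside log2 differences are standard errors (SE) of limma with n = 3 arrays per group. The labels do not say whether replicates are separate cultures, passages or lines, so the p-values measure only the spread between these arrays. With 3 arrays against 3, the smallest two-sided exact permutation p for a single gene is 0.1. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

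The comparisons, their tests, the alternatives, 33 gene lists of pathways, endothelial subtypes and other cell types, and the rule for naming genes were chosen before the data were examined, apart from the alternatives and tests that the closing section names as later. Of 576 genes on the lists, 551 were measured. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance in a single direction. The p-values of lists were adjusted over the 33 lists of a comparison. The genes named are Fzd4 and Ndp, the 8 largest rises and the 8 largest falls of a comparison among genes past the threshold whose arrays do not overlap between the groups, up to 4 members of each list past the threshold, and Axin2, Lef1, Sox7, Sox17, Sox18, Cldn5, Plvap, Slc38a5 and Cdh5. Symbols of uncharacterised genes were counted but not named. Genes that responded to Norrin were compared with 10000 random gene sets matched on expression in 50 bins.

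The alternatives were quantile normalization within a fit, median centring, the mean of a gene's probe sets, probe sets without cross-hybridization suffixes, only genes above the median level, all 24 arrays in 1 fit, only the arrays compared, a trended robust variance, a 2-fold minimum, the replicate number as a block, and leaving out each array in turn. Equal replicate numbers were checked for pairing by correlating, over genes, the deviation of each array from its group mean with that of the array of the same number in the other group. These correlations were 0.24 to 0.72 in the single cultures, 0.10 to 0.36 for Norrin in wild type, and 0.14 to 0.37 for the genotypes with Norrin-expressing cells. An array correlated best with its own number in only 2 of 6 checks for Matrigel in wild type and 3 in Fz4-/-. The count was 4 for genotype on gelatin, 5 on Matrigel, 4 for Norrin in wild type and 6 for genotype with Norrin-expressing cells. Positive correlations alone therefore do not show that equal numbers are pairs. The procedure was tested on simulated data of the same size with known changes.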

Results

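The 24 arrays measured gene expression in 8 groups of 3 mouse retinal endothelial cell cultures. The lines came from adult mice of mixed gender on a mixed C57Bl6/129 background that carry a temperature-sensitive SV40 large T antigen, which lets primary cells divide in culture. They were wild type or lacked frizzled-4 (Fz4-/-), the receptor for the secreted ligand Norrin. Cells of each genotype were grown on gelatin, on Matrigel (a basement membrane extract) for 6 hours after 24 hours in 1% serum, together with a control line of human HEK293 cells, or together with HEK293 cells that make Norrin. RNA of the co-cultures was a mixture of mouse and human RNA in about equal parts, per the labels, so probe sets there also meet human transcripts. RNA was collected at 37 °C. In 6 of the 8 groups, replicates 2 and 3 lay closer to each other than to replicate 1, with a standard deviation of gene differences of 0.147 to 0.193 log2 against 0.299 to 0.354. In the Fz4-/- co-cultures all pairs lay at 0.182 to 0.226.

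Fzd4 and Ndp were read first, as checks on the labels. Fzd4, which encodes frizzled-4, was at 8.70 ± 0.35 log2 (SD, n = 3) in wild type and 5.06 ± 0.44 in Fz4-/- cells on gelatin. In co-culture with control HEK293 cells it was at 6.24 ± 0.05 and 2.82 ± 0.13. Fzd4 was lower in Fz4-/- by -3.64 ± 0.22 on gelatin (SE, adjusted p = 7.77e-07), -3.74 ± 0.22 on Matrigel, -3.42 ± 0.10 with control cells and -3.64 ± 0.10 with Norrin-expressing cells. A further pair of Fzd4 probe sets differed by -2.62 and -1.18 on gelatin. The labels do not say which part of the gene is missing. Ndp, which encodes mouse Norrin, stayed between 2.18 and 3.23 in every group, near the lowest values of the arrays. It did not set the Norrin-expressing co-cultures apart, so it gave no check on that label.

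On gelatin, which asks how the lines differ without Norrin, the largest falls in Fz4-/- cells were in Ifi202b, an interferon-inducible gene, at -6.90 ± 0.29 (SE, n = 3 per group), and in Hoxd8, a homeobox transcription factor, at -6.33 ± 0.17. Ifi202b lay at 3.41 in Fz4-/-, near the lowest values of the arrays, so the size of its fall is less sure than its direction. Sox17, an endothelial transcription factor of the SoxF group, fell by 4.82 ± 0.18, and its other probe set by 6.41. The related Sox7 (0.55 ± 0.29) and Sox18 (0.45 ± 0.23) did not pass the test, although Sox18 passed at 0.69 without wild type gelatin replicate 1 (adjusted p = 0.0455, alternatives from 0.0302 to 1). The largest rises were in Fam167b (6.00 ± 0.19), Rps4l (5.27 ± 0.26), Bst1 (4.98 ± 0.59) and Casp1, an inflammatory caspase (4.36 ± 0.21). Thy1, a surface glycoprotein, rose by 4.32 ± 0.22. Of 28 measured interferon response genes, 18 fell, 0 rose and 10 did not pass (24 down adjusted over the list alone), with a median of -2.0. Cxcl10 (-4.09 ± 0.89), Ifit3 (-3.15 ± 0.57) and Ifit1 (-3.06 ± 0.50) are examples. The list's adjusted p was 1.46e-13, and adjusted p = 0.761 with an estimated correlation. Of 35 cell cycle genes, 15 fell and 20 did not pass (32 down adjusted over the list alone), with Rrm2, a subunit of ribonucleotide reductase, at -1.77 ± 0.41. The list gave adjusted p = 3.11e-11, and adjusted p = 0.761 with an estimated correlation. Its mean level was 9.72 to 9.89 in the wild type arrays and 7.65 to 9.09 in the Fz4-/- arrays (mean 8.60). A single Fz4-/- array stood far below the others, so the size of this fall rests in part on it.

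Arterial markers were lower in part on gelatin. Of 15 measured, 6 fell and 9 did not pass (6 down adjusted over the list alone), among them Unc5b (-1.67 ± 0.20), the Notch ligand Dll4 (-1.66 ± 0.25) and Nrp1 (-1.43 ± 0.21). The list passed at adjusted p = 0.000376, with adjusted p = 0.0763 with an estimated correlation. Lymphatic markers gave 2 up, 0 down and 6 not past of 8 (2 up adjusted over the list alone, list adjusted p = 0.495), with Lyve1 at 2.5 ± 0.44. Venous markers gave 3 up, 1 down and 6 not past of 10 (3 up and 1 down adjusted over the list alone, list adjusted p = 0.428), with the receptor Nrp2 at 2.38 ± 0.26. Selp, which encodes P-selectin, rose by 3.3 ± 0.15 and Foxf2 by 2.07 ± 0.14. Of 24 barrier and transporter genes, 2 rose, 0 fell and 22 did not pass (2 up adjusted over the list alone), with list adjusted p = 0.977. Plvap, a component of endothelial fenestrae, was higher by 2.02 ± 0.53 (adjusted p = 0.0247). Without Fz4-/- gelatin replicate 1 it was 1.64 (adjusted p = 0.094), without wild type gelatin replicate 2 it was 1.75 (0.10), and without replicate 3 it was 1.74 (0.102), and its alternatives ranged from 1.99e-06 to 0.102. In order of replicate number, Plvap lay at 13.23, 12.1 and 12.05 in Fz4-/- and at 11.53, 9.90 and 9.88 in wild type, higher in Fz4-/- at each number. Cldn5 (-0.84 ± 0.53), Slc38a5 (-0.23 ± 0.13) and Cdh5 (-0.06 ± 0.09) did not pass. Of 24 Wnt/beta-catenin target genes, 1 rose, 2 fell and 21 did not pass (2 up and 3 down adjusted over the list alone, list adjusted p = 0.540). Ccn4 fell by 2.59 ± 0.25, while Axin2 (-0.19 ± 0.11) and Lef1 (-0.04 ± 0.09) did not pass. In all, 2719 of 18193 genes passed with limma, 1312 higher and 1407 lower in Fz4-/-. The count was 4138 with replicate number as a block, 1796 without wild type gelatin replicate 3 and 1800 without replicate 2. With replicates 2 and 3 averaged into 1 sample it was 667, and without replicate 1 of every group 4911, alternatives chosen after seeing the data.

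**Figure D1:**
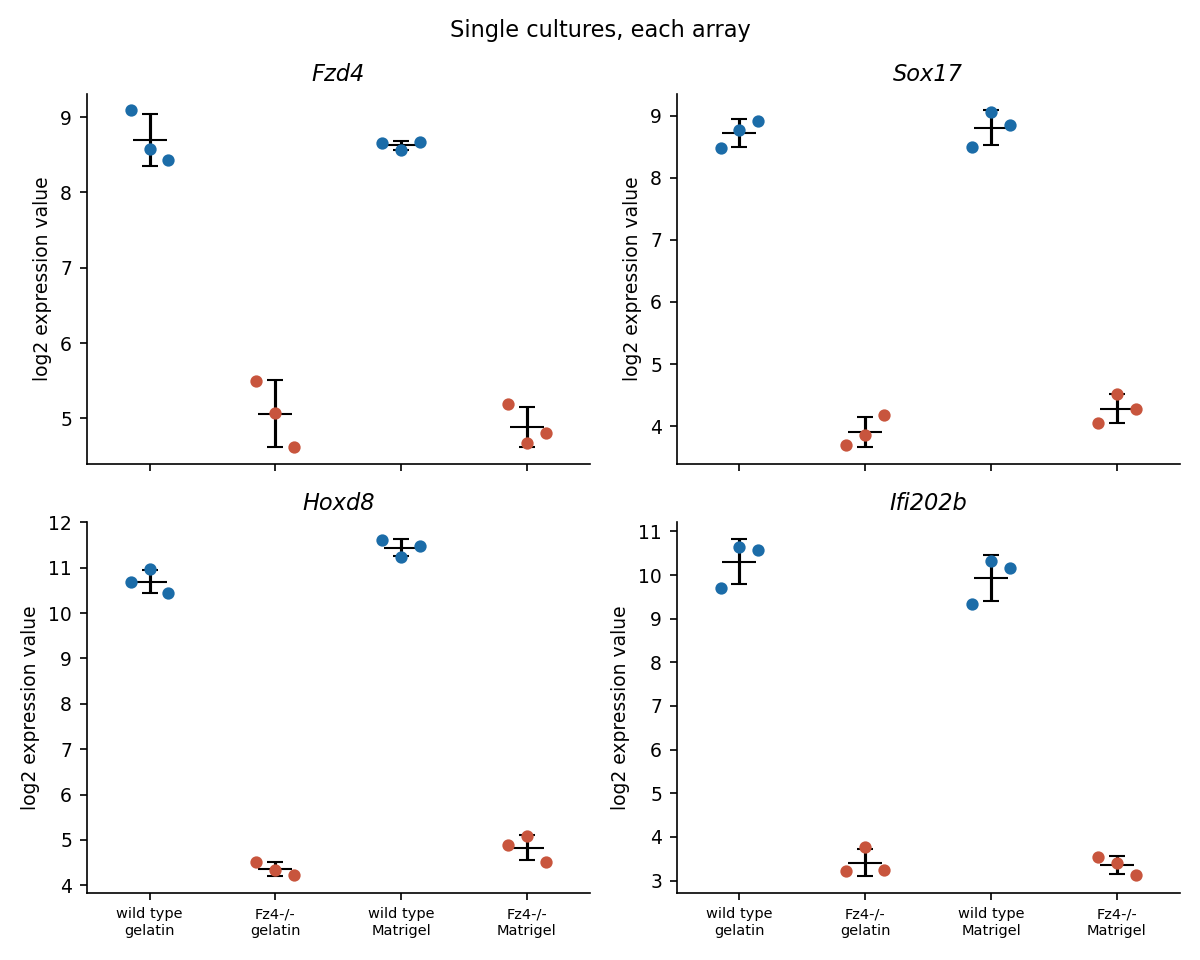
Log2 intensity of Fzd4, Sox17, Hoxd8 and Ifi202b in the 12 single cultures, with a point per array and the group mean ± SD as bars (n = 3 per group). Fzd4 lies at 8.43 to 9.09 in wild type and at 4.62 to 5.50 in Fz4-/- cells on gelatin, and each gene is lower in every Fz4-/- array than in every wild type array.

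On Matrigel, the same leading genes differed between genotypes. Falls were in Hoxd8 (-6.62 ± 0.17), Ifi202b (-6.58 ± 0.29) and Sox17 (-4.52 ± 0.18; SE, n = 3 per group), while Fam167b rose by 6.21 ± 0.19 and Klk8, a serine protease, by 5.77 ± 0.33. Ankrd1, a stretch-responsive YAP/TAZ target, fell by 4.34 ± 0.26, and Selp rose by 4.33 ± 0.15. Interferon response genes gave 18 down, 0 up and 10 not past of 28 (22 down adjusted over the list alone, median -1.89), with Ifit1 at -2.92 ± 0.50 and Usp18 at -2.56 ± 0.42. The list had adjusted p = 6.52e-13, and adjusted p = 0.731 with an estimated correlation. Cell cycle genes gave 18 down and 17 not past of 35 (31 down adjusted over the list alone, median -1.33), with Rrm2 at -1.91 ± 0.41. That list had adjusted p = 6.99e-13, and adjusted p = 0.731 with an estimated correlation. Its mean level was 9.82 to 9.92 in the wild type arrays and 7.75 to 8.99 in the Fz4-/- arrays (mean 8.58). As on gelatin, a single Fz4-/- array stood far below the others. Arterial markers gave 8 down and 7 not past of 15 (1 up and 9 down adjusted over the list alone), with Nrp1 at -1.48 ± 0.21, Unc5b at -1.40 ± 0.20 and Bmx at -1.32 ± 0.23. Their list had adjusted p = 0.000433, and adjusted p = 0.0800 with an estimated correlation. Venous markers gave 3 up, 1 down and 6 not past of 10 (5 up and 1 down adjusted over the list alone), with Nrp2 at 2.48 ± 0.26 and Nr2f2, a venous transcription factor, at 1.07 ± 0.13. The venous list had adjusted p = 0.0356, and adjusted p = 0.542 with an estimated correlation. A cholesterol synthesis list passed at 0.0356 with a median of -0.31 but only 1 of 19 members past the threshold (0 adjusted over the list alone), and adjusted p = 0.822 with an estimated correlation. In all, 2854 genes passed, 1258 higher and 1596 lower in Fz4-/-, with 4379 under the replicate block, 736 with replicates 2 and 3 averaged and 4857 without replicate 1 of every group. Between gelatin and Matrigel, 857 genes were higher in both comparisons (90.7 by chance for independent lists), 1117 were lower in both (123 by chance), and 3 were called in opposite directions.

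Matrigel against gelatin compares cells put on a basement membrane extract for 6 hours after 24 hours in 1% serum with cells on gelatin, for which the labels give no such starvation. Effects of the extract, of low serum and of time in culture can therefore not be parted here. In wild type cells Slc40a1, an iron exporter, rose by 3.08 ± 0.54 (SE, n = 3 per group) and Cxcr4, a chemokine receptor of sprouting endothelium, by 2.11 ± 0.23, while F3, which encodes tissue factor, fell by 2.87 ± 0.54 and Osr1 by 2.85 ± 0.13. In Fz4-/- cells Slc40a1 rose by 3.54 ± 0.54, Serpinb1a by 3.46 ± 0.28 and Cxcr4 by 1.93 ± 0.23, while falls were in Npr3 (-3.46 ± 0.27), Ankrd1 (-2.90 ± 0.26) and F3 (-2.36 ± 0.54). YAP/TAZ target genes, which follow cell spreading, tension and serum, fell in both lines. In wild type 10 of 16 fell, 0 rose and 6 did not pass (11 down adjusted over the list alone, median -0.836), with Ankrd1 at -2.0 ± 0.26 and Thbs1 at -1.22 ± 0.17. In Fz4-/- 10 of 16 fell and 6 did not pass (11 down adjusted over the list alone, median -0.812), with Ccn1 at -1.80 ± 0.32 and Thbs1 at -1.60 ± 0.17. Actin cytoskeleton and SRF target genes gave 14 down and 7 not past of 21 in wild type (15 down adjusted over the list alone) and 13 down and 8 not past in Fz4-/- (13 down adjusted over the list alone). Zyx, a focal adhesion protein, changed by -1.20 ± 0.10 and -1.36 ± 0.10, and Fhl2 by -1.24 ± 0.12 and -1.18 ± 0.12. Both lists also passed with an estimated correlation, at adjusted p = 0.0438 in wild type and adjusted p = 0.0327 in Fz4-/-.

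Pan-endothelial markers rose in part on Matrigel, with 4 up, 0 down and 22 not past of 26 in wild type (4 up adjusted over the list alone) and 6 up, 0 down and 20 not past in Fz4-/- (9 up adjusted over the list alone). Clec14a changed by 1.15 ± 0.12 and 0.93 ± 0.12 and the angiopoietin receptor Tek by 0.80 ± 0.12 and 0.98 ± 0.12. That list had adjusted p = 0.0159 and 0.00281, and adjusted p = 0.751 and adjusted p = 0.511 with an estimated correlation. Immediate early genes gave 1 up, 6 down and 13 not past of 20 in wild type (1 up and 8 down adjusted over the list alone), with Dusp5 at -1.69 ± 0.21 and Fosl2 at -1.18 ± 0.09. They passed at adjusted p = 0.0385, and adjusted p = 0.781 with an estimated correlation. In Fz4-/- cells the unfolded protein and amino acid stress list gave 1 up, 7 down and 13 not past of 21 (2 up and 13 down adjusted over the list alone), with Chac1 at -1.39 ± 0.24 and Psat1 at -1.01 ± 0.17. It passed at adjusted p = 0.0151, and adjusted p = 0.511 with an estimated correlation. Matrix proteases gave 5 up and 14 not past of 19 in Fz4-/- (5 up and 2 down adjusted over the list alone), with Adamts4 at 1.62 ± 0.18 and Adamts1 at 1.35 ± 0.24, and adjusted p = 0.0425, or adjusted p = 0.553 with an estimated correlation. Among Wnt/beta-catenin target genes Lef1 fell by 1.17 ± 0.09 in wild type and by 1.11 ± 0.09 in Fz4-/-, and 9 of 24 fell in wild type and 6 in Fz4-/- (9 and 7 down adjusted over the list alone), without the list passing (adjusted p = 0.137 and 0.398). In wild type 3356 genes passed, 1221 up and 2135 down, and in Fz4-/- 3592 passed, 1439 up and 2153 down. The counts were 2137 without wild type Matrigel replicate 2, and 2351 and 2335 without Fz4-/- gelatin replicates 2 and 3. Averaging replicates 2 and 3 gave 574 and 712, and leaving out replicate 1 of every group gave 5088 and 5498.

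The response to Matrigel differed between genotypes in 3 genes by limma's test of the difference. Kcnn4, a calcium-activated potassium channel, changed by -0.24 in wild type (not past) and 1.26 in Fz4-/-, a difference of 1.5 ± 0.14 (SE, n = 3 per group, adjusted p = 0.00458). Gadd45a, a stress-induced growth arrest gene, rose by 0.37 ± 0.09 in wild type and fell by 0.89 ± 0.09 in Fz4-/-, a difference of -1.26 ± 0.13 (adjusted p = 0.00702). Its rise in wild type lost its call without wild type Matrigel replicate 3 (0.30, adjusted p = 0.0731), gelatin replicate 1 (0.32, 0.0610) or gelatin replicate 3 (0.36, 0.0521), with alternatives from 0.00956 to 1. Tbx18 changed by -0.23 (not past) and -1.41, a difference of -1.18 ± 0.15 (adjusted p = 0.0359). The Tbx18 call was lost without any 1 of the 12 arrays other than Fz4-/- Matrigel replicate 1 and wild type gelatin replicate 3, with values of -1.21 to -1.11 and adjusted p from 0.0800 to 0.147, and its alternatives ranged from 0.00814 to 0.147. Lists of matrix proteases (median difference 0.14), NF-kB and inflammatory adhesion genes (0.374) and unfolded protein genes (-0.227) passed at adjusted p = 0.00106, 0.00106 and 0.00215 without a member past the threshold over all genes (4, 1 and 0 up adjusted over the list alone). With an estimated correlation they had adjusted p = 0.402, adjusted p = 0.626 and adjusted p = 0.402. The count was 8 with replicate number as a block, 5 without Fz4-/- Matrigel replicate 1, 5 without wild type gelatin replicate 3 and 61 without replicate 1 of every group. With replicates 2 and 3 averaged, limma called 0 genes, with 340 at an unadjusted p below 0.05.

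**Figure D2:**
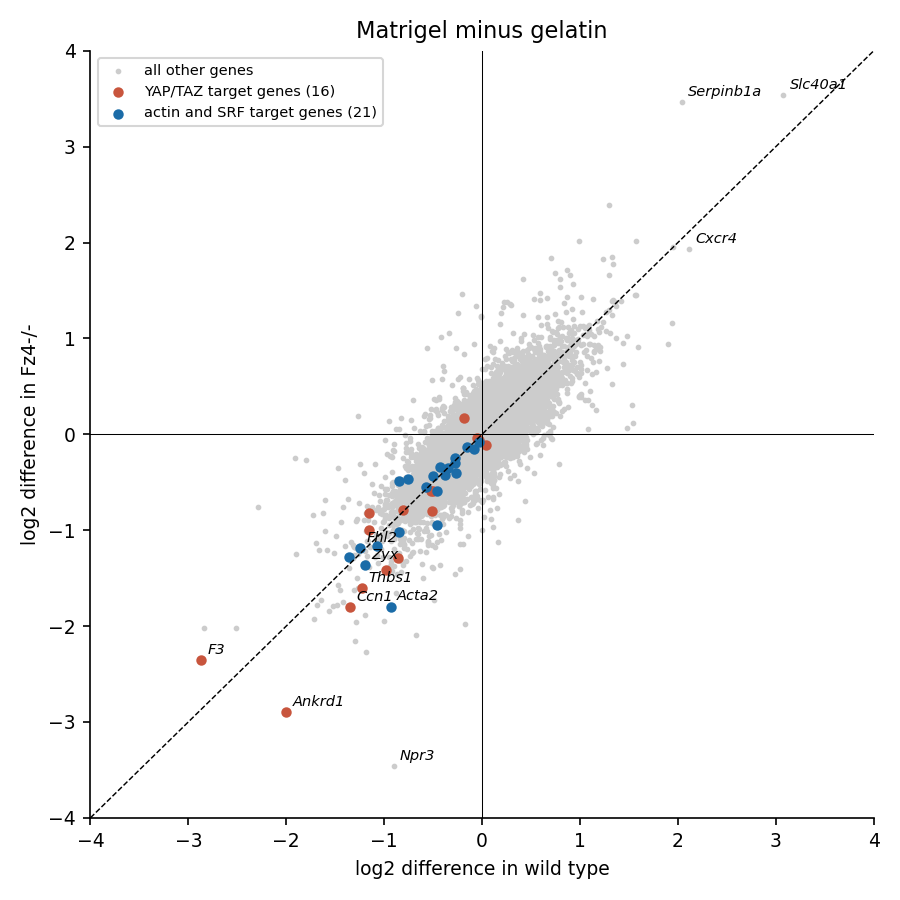
Log2 difference between Matrigel and gelatin in Fz4-/- cells against that in wild type cells, a point per gene, with the 16 YAP/TAZ and 21 actin and SRF target genes coloured. Genes follow each other in both lines, with 808 called higher in both and 1397 called lower in both.

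Norrin-expressing against control HEK293 cells asks how wild type cells respond to a neighbouring line that makes the ligand. No group parts Norrin from other differences between these HEK293 lines. Lcn2, which encodes an iron-binding protein of acute inflammation, fell by 5.80 ± 0.16 (SE, n = 3 per group, adjusted p = 5.36e-14), from 8.97 to 3.17. The neutrophil chemokines Cxcl5 (-4.76 ± 0.12), Cxcl2 (-4.42 ± 0.14) and Cxcl1 (-3.70 ± 0.10) and the adhesion molecule Selp (-2.91 ± 0.16) fell with it. The largest rises were in the matricellular gene Sparcl1 (2.97 ± 0.18), the secreted Wnt modulator Sfrp2 (2.81 ± 0.23), Cthrc1 (2.27 ± 0.16), the semaphorin and VEGF co-receptor Nrp1 (2.17 ± 0.21) and the endothelial lectin Clec14a (2.13 ± 0.14). Of 22 NF-kB and inflammatory adhesion genes, 16 fell, 0 rose and 6 did not pass (18 down adjusted over the list alone, median -0.812), at adjusted p = 4.29e-26, and adjusted p = 0.00102 with an estimated correlation. Of 26 pan-endothelial markers, 19 rose, 1 fell and 6 did not pass (21 up and 1 down adjusted over the list alone, median 0.749), with Fli1 at 1.45 ± 0.13, Ramp2 at 1.44 ± 0.14, Icam2 at 1.29 ± 0.13 and Cdh5, which encodes VE-cadherin, at 1.06 ± 0.15. They had adjusted p = 7.49e-19, and adjusted p = 0.110 with an estimated correlation. Of 19 cholesterol synthesis genes, 12 rose and 7 did not pass (13 up adjusted over the list alone, median 0.607), with Sqle at 1.96 ± 0.21, Msmo1 at 1.71 ± 0.13 and Idi1 at 1.31 ± 0.11, at adjusted p = 7.51e-18, and adjusted p = 0.0396 with an estimated correlation. Of 17 p53 target genes, 6 fell and 11 did not pass (10 down adjusted over the list alone), with Pmaip1 at -1.33 ± 0.12 and Mdm2 at -0.93 ± 0.13, at adjusted p = 1.5e-07, and adjusted p = 0.0396 with an estimated correlation.

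Lists of matrix genes, Wnt receptors and Wnt targets were read next in wild type cells with Norrin. Of 22 basement membrane and matrix genes, 11 rose, 1 fell and 10 did not pass (12 up and 1 down adjusted over the list alone), with the crosslinking enzyme Lox at 1.52 ± 0.14, Col5a2 at 1.35 ± 0.14 and Fn1 at 1.00 ± 0.10. The list had adjusted p = 9.07e-09, and adjusted p = 0.145 with an estimated correlation. Of 20 Wnt receptors and co-receptors, 4 rose and 16 did not pass (4 up adjusted over the list alone), with Fzd6 at 1.68 ± 0.11, Reck at 1.13 ± 0.16 and Lgr4 at 0.88 ± 0.13, while Fzd4 was at 0.16 ± 0.10 (not past). They had adjusted p = 0.00596, and adjusted p = 0.221 with an estimated correlation. Of 24 Wnt/beta-catenin target genes, 2 rose, 1 fell and 21 did not pass (2 up and 2 down adjusted over the list alone, list adjusted p = 0.718), with Fgf18 at 0.85 ± 0.13, Sp5 at 0.80 ± 0.14 and Axin2 at 0.06 ± 0.10 (not past). Of the SoxF genes Sox18 rose by 0.92 ± 0.18, Sox7 was at 0.24 ± 0.16 and Sox17 at 0.31 ± 0.17 (both not past), and the other probe set of Sox17 was at 1.34 (adjusted p over probe sets 4.17e-06). The first Sox17 probe set lay low with control cells, at 3.90 to 4.62 in wild type against 3.41 to 3.70 in Fz4-/-. A response could be missed there. Cldn5 was at 0.13 ± 0.12 and Slc38a5 at -0.01 ± 0.12 (both not past). Another 8 lists passed with the preset correlation, none of them with an estimated correlation, where the adjusted p values ran from 0.0668 (tip cell genes) to 0.496 (interferon response genes). Mouse counterparts of 18 genes abundant in HEK293 cells gave 0 up, 2 down and 16 not past (2 down adjusted over the list alone, median 0.0017, list adjusted p = 0.479). In all, 1741 genes passed, 981 up and 760 down, 691 with replicates 2 and 3 averaged and 761 with only the arrays compared.

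**Figure D3:**
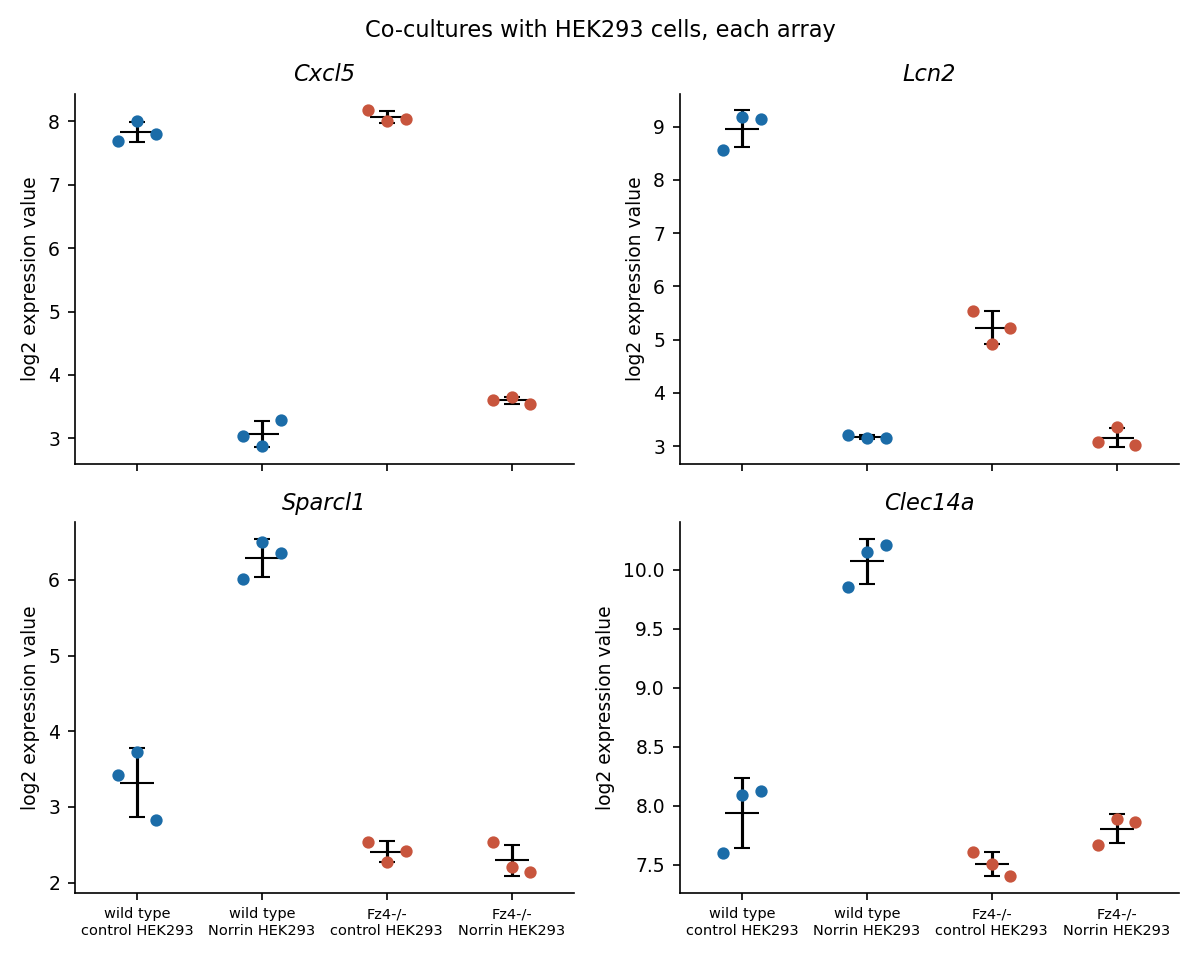
Log2 intensity of Cxcl5, Lcn2, Sparcl1 and Clec14a in the 12 co-cultures, with a point per array and the group mean ± SD as bars (n = 3 per group). Cxcl5 is lower with Norrin-expressing cells in both genotypes, from 7.83 to 3.07 in wild type and from 8.07 to 3.60 in Fz4-/- cells, whereas Sparcl1 goes from 3.32 to 6.29 in wild type and from 2.41 to 2.30 in Fz4-/- cells.

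In Fz4-/- cells the chemokine genes also fell with Norrin-expressing cells. Changes were -4.47 ± 0.12 for Cxcl5 (SE, n = 3 per group), -2.56 ± 0.14 for Cxcl2, -2.55 ± 0.10 for Cxcl1, -2.07 ± 0.16 for Lcn2, -1.55 ± 0.14 for Ccl7 and -1.31 ± 0.19 for the endothelial selectin Sele. Fst, an inhibitor of activin, rose by 1.07 ± 0.15, the receptor Kit by 1.05 ± 0.15, St8sia4 by 1.00 ± 0.10 and Fosl2 by 0.98 ± 0.11. Of 22 NF-kB and inflammatory adhesion genes, 7 fell, 1 rose and 14 did not pass (12 down and 1 up adjusted over the list alone, median -0.318), at adjusted p = 6.48e-22, and adjusted p = 0.00193 with an estimated correlation. Of 26 pan-endothelial markers, 1 rose and 25 did not pass (3 up adjusted over the list alone, median 0.219), at adjusted p = 3.14e-09, and adjusted p = 0.338 with an estimated correlation. Mouse counterparts of genes abundant in HEK293 cells gave 1 down and 17 not past of 18 (4 down adjusted over the list alone, median -0.0969), at adjusted p = 0.0043, and adjusted p = 0.167 with an estimated correlation. The other 9 lists that passed with the preset correlation had at most 2 members past the threshold, and adjusted p values of 0.167 to 0.549 with an estimated correlation. In all, 83 genes passed, 39 up and 44 down. Leaving out 1 array gave 46, 36 and 37 (Fz4-/- control replicates 1, 2 and 3) and 50, 39 and 36 (Norrin replicates 1, 2 and 3), averaging replicates 2 and 3 gave 10, only the arrays compared gave 162, leaving out replicate 1 of every group gave 118, and all 24 arrays in 1 fit gave 44, without Lcn2, Ccl7, Sele, Fst and Kit. Between genotypes, 21 genes rose with Norrin in both (2.10 by chance) and 27 fell in both (1.84 by chance). Another 2 were called in opposite directions, Fst (-0.68 ± 0.15 in wild type and 1.07 ± 0.15 in Fz4-/-) and Ptgs2 (-0.67 ± 0.13 and 0.89 ± 0.13).

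The difference between genotypes in the response to Norrin-expressing cells asks which responses depend on genotype, and it spans a pair of array sets with unlike value distributions. Lcn2 fell less in Fz4-/- cells, a difference of 3.73 ± 0.23 (SE, n = 3 per group, adjusted p = 1.1e-07), as did Cxcl2 (1.86 ± 0.19, adjusted p = 4.33e-05), Selp (1.95 ± 0.23) and the mitochondrial antioxidant enzyme Sod2 (1.84 ± 0.15). Lcn2 and Cxcl2 ended near the lowest values of the arrays in both genotypes, which limits how far they could fall from a lower start, and levels between genotypes share their groups with the array sets. Lcn2 went from 8.97 to 3.17 in wild type and from 5.23 to 3.16 in Fz4-/-, Cxcl2 from 7.52 to 3.10 and from 5.52 to 2.96, and Sod2 from 8.34 to 6.33 and from 6.39 to 6.22. Cxcl1 differed by 1.15 (adjusted p = 0.000221), and Cxcl5 by 0.30 (adjusted p = 0.540, not past). Cxcl5 also ended low on the arrays in both genotypes, so a difference in its fall could be missed. Sparcl1 (-3.08 ± 0.26), Sfrp2 (-2.79 ± 0.32), Nrp1 (-1.95 ± 0.29) and Clec14a (-1.84 ± 0.20) rose in wild type and differed between genotypes. Sparcl1 (2.41 and 2.30) and Sfrp2 (2.28 and 2.29) stayed near the lowest values in both Fz4-/- co-cultures, so a small response there could be missed. Of 19 cholesterol synthesis genes, 9 responded lower in Fz4-/-, 0 higher and 10 did not pass (9 lower adjusted over the list alone, median -0.50), with Sqle at -1.71 ± 0.29 and Msmo1 at -1.36 ± 0.18, at adjusted p = 1.5e-12, and adjusted p = 0.0582 with an estimated correlation. NF-kB and inflammatory adhesion genes gave 6 higher and 16 not past of 22 (11 higher and 1 lower adjusted over the list alone), with Ptgs2 at 1.56 ± 0.18. The p53 targets gave 3 higher and 14 not past of 17 (10 higher adjusted over the list alone), with Pmaip1 at 1.38 ± 0.17. Each of these last lists had adjusted p = 6.94e-11, and adjusted p = 0.0173 with an estimated correlation. Pan-endothelial markers gave 8 lower, 1 higher and 17 not past of 26 (12 lower and 1 higher adjusted over the list alone), with Icam2 at -1.22 ± 0.18 and Tek at -1.07 ± 0.17, at adjusted p = 6.74e-10, and adjusted p = 0.221 with an estimated correlation. Their mean level went from 7.17 to 7.87 in wild type and from 7.74 to 7.965 in Fz4-/-. The list in Fz4-/- thus started near the level that wild type reached. BMP and TGF-beta response genes gave 4 lower and 15 not past of 19 (1 higher and 8 lower adjusted over the list alone), with Smad6 at -1.21 ± 0.24 and Id1 at -1.01 ± 0.15, at adjusted p = 4.8e-08, and adjusted p = 0.110 with an estimated correlation. In all, 385 genes passed, 159 higher and 226 lower. The count was 241, 232 and 255 without Fz4-/- control replicates 1, 2 and 3, 242 and 248 without Fz4-/- Norrin replicates 2 and 3, and 90 with replicates 2 and 3 averaged.

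**Figure D4:**
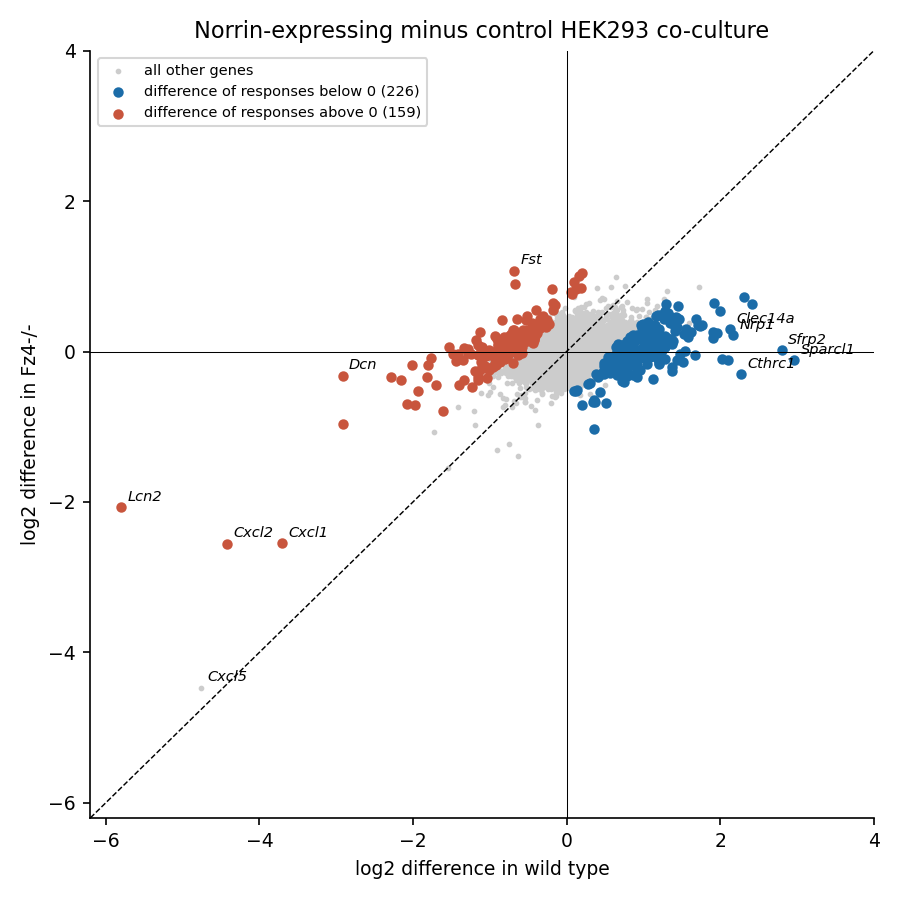
Log2 difference between Norrin-expressing and control HEK293 co-culture in Fz4-/- cells against that in wild type cells, a point per gene, with the 226 genes of a lower and the 159 genes of a higher response in Fz4-/- coloured. Cxcl5 lies at -4.76 and -4.47, whereas Lcn2 lies at -5.80 and -2.07.

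Fz4-/- against wild type in co-culture shares its groups with the array sets, so these differences cannot be told apart from a difference between the sets. With control HEK293 cells Slfn4 was higher by 6.50 ± 0.10 (SE, n = 3 per group) and Lyve1 by 5.78 ± 0.10, while Ubd was lower by -6.82 ± 0.10 and Aldh1a1, a retinaldehyde dehydrogenase, by -6.14 ± 0.12. With Norrin-expressing cells Slfn4 was at 6.93 ± 0.11, Lyve1 at 6.47 ± 0.10, Aldh1a1 at -7.51 ± 0.12 and Ubd at -7.18 ± 0.10. Tip cell genes gave 10 higher, 6 lower and 2 not past of 18 with control cells, with Angpt2 at 2.14 ± 0.16 and Plaur at 2.78 ± 0.15, at adjusted p = 0.000158, and adjusted p = 0.0454 with an estimated correlation. Cholesterol synthesis genes gave 0 higher, 15 lower and 4 not past of 19 with control cells and 17 lower and 2 not past with Norrin-expressing cells, with Sqle at -2.36 ± 0.21 in the latter, and adjusted p = 0.474 and adjusted p = 0.164 with an estimated correlation. With control cells 9253 genes passed, 2199 higher and 7054 lower, and with Norrin-expressing cells 9079 passed, 2099 higher and 6980 lower, around all-gene medians of -0.201 and -0.202. After quantile normalization within the fit the genes split into 3576 higher and 4309 lower, and 3549 higher and 3936 lower. Genotype on gelatin and with control cells shared 405 higher genes (159 by chance for independent lists) and 758 lower genes (546 by chance). Another 520 were called in opposite directions. With control cells, Ifi202b lay at 2.66 to 2.84 in wild type and at 2.48 to 2.705 in Fz4-/-. In wild type on gelatin it lay at 9.71 to 10.64. Sox17 lay at 3.90 to 4.62 and at 3.41 to 3.70 with control cells, against 8.48 to 8.91 in wild type on gelatin.

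Genes that changed with Norrin-expressing cells in wild type co-cultures were then followed in the single cultures, which are separate arrays. The 981 genes that rose with Norrin had a median difference between Fz4-/- and wild type of 0.0473 log2 on gelatin (percentile 100 of 10000 random sets matched on expression) and 0.0309 on Matrigel (percentile 95.9). With the mean of all probe sets the Matrigel value turned to -0.00169 (percentile 10.6). The 760 genes that fell with Norrin had medians of -0.0465 on gelatin and -0.0473 on Matrigel (percentile 0 in both). With all 24 arrays in 1 fit these were 0.000442 (percentile 9.19) and -0.00923 (percentile 3.52). Random sets for the risen genes lay between 0.00047 and 0.0353 on gelatin and between -0.0035 and 0.0323 on Matrigel, and for the fallen genes between -0.0063 and 0.0348 and between -0.0115 and 0.0345. Of the risen genes 157 were called higher and 112 lower in Fz4-/- on gelatin, and of the fallen genes 81 higher and 107 lower. On Matrigel 143 of the risen genes were called higher and 148 lower, and 66 of the fallen genes higher and 126 lower. Over all 18193 genes, 1312 were called higher and 1407 lower on gelatin, and 1258 and 1596 on Matrigel. The random sets do not keep the correlation between genes, and these medians are small beside the median SE of a gene, 0.118.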

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

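The tests of a smaller share of mouse RNA, of array distributions, of room to fall, of fibroblast markers and of differences between lines were chosen only after the result was seen.

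The response to Norrin-expressing cells differed between genotypes in 385 genes. The difference, Fz4-/- minus wild type, was above 0 in Lcn2 (3.73), Dcn (2.60), Cd68 (1.95), Selp (1.95), Cxcl2 (1.86), Sod2 (1.84), Micall2 (1.77), Fst (1.76), Ptgs2 (1.56), Ccl5 (1.44), Pmaip1 (1.38), Mdm2 (1.14), Asns (1.01), Ddit3 (0.89), Hspa5 (0.77) and Gadd45a (0.70), and for Lcn2 and Cxcl2 this is a smaller fall in Fz4-/-. Without 1 array the call of Gadd45a was lost in 5 cases, at 0.64 without Fz4-/- Norrin replicate 1 (adjusted p = 0.0582), 0.69 without its replicate 2 (0.0507), 0.68 and 0.66 without Fz4-/- control replicates 1 and 2 (0.0603 for each), and 0.63 without wild type control replicate 2 (0.0532), and its alternatives ranged from 0.00793 to 1. The difference was below 0 with Sparcl1 at -3.08, Sfrp2 at -2.79, Cthrc1 at -2.56, Ogn at -2.22, Ackr3 at -2.12, Nrp1 at -1.95, Clec14a at -1.84, Tmem158 at -1.78, Lox at -1.66, Bmx at -1.24, Icam2 at -1.22, Ramp2 at -1.11 and Tek at -1.07. It was also below 0 in Col3a1 (-0.94), Acta2 (-0.91), Thy1 (-0.91), S100a4 (-1.32), Eln (-0.87), Fn1 (-0.74), Smad6 (-1.21), Id1 (-1.01), Id2 (-1.0), Sqle (-1.71), Msmo1 (-1.36), Stard4 (-1.25), Cyp51 (-1.20), Reck (-1.49) and Fzd6 (-1.24). Col5a2 was at -0.89, with -0.85 without Fz4-/- Norrin replicate 1 (adjusted p = 0.058), -0.87 without Fz4-/- control replicate 2 (0.0603), -0.82 and -0.86 without wild type Norrin replicates 2 and 3 (0.053 and 0.0507), and alternatives from 2.45e-05 to 1. Id3 was at -0.72, with -0.65 without wild type Norrin replicate 3 (adjusted p = 0.0511) and alternatives from 0.00134 to 1. Lgr4 was at -0.86, with -0.81 without Fz4-/- Norrin replicate 2 (adjusted p = 0.0582), -0.81 and -0.76 without Fz4-/- control replicates 2 and 3 (0.0603 and 0.063), -0.79 without wild type Norrin replicate 3 (0.0536), and alternatives from 0.00515 to 1.

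Of 33 gene lists, 12 passed for the difference of the Norrin responses with the preset correlation and 2 of these with an estimated correlation. Those 2 were NF-kB and inflammatory adhesion genes (median difference 0.377) and p53 targets (0.494), each at adjusted p = 0.0173 with an estimated correlation. The other lists lost their call, with medians of 0.272 for unfolded protein genes (adjusted p = 0.0582 with an estimated correlation), -0.50 for cholesterol synthesis (0.0582), -0.464 for pan-endothelial markers (0.221), -0.438 for BMP and TGF-beta response genes (0.110), -0.428 for SoxF factors (0.358) and -0.285 for basement membrane and matrix (0.271). The rest that lost it were actin and SRF targets (-0.268, adjusted p = 0.221 with an estimated correlation), Wnt receptors (-0.198, 0.110), arterial markers (-0.148, 0.0991) and fibroblast markers (-0.103, 0.120).

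The Matrigel response differed in 3 genes, namely Kcnn4 (1.5), Gadd45a (-1.26) and Tbx18 (-1.18). Tbx18 kept its call without Fz4-/- Matrigel replicate 1 or wild type gelatin replicate 3 and lost it without any other array, with values of -1.21 to -1.11 and adjusted p from 0.0800 to 0.147, and its alternatives ranged from 0.00814 to 0.147. Lists of matrix proteases (0.14), NF-kB and inflammatory adhesion genes (0.374) and unfolded protein genes (-0.227) passed in the same comparison with the preset correlation only, without a member past the threshold. They had adjusted p = 0.402, adjusted p = 0.626 and adjusted p = 0.402 with an estimated correlation, and fry called 0 lists.

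Of 10092 probe sets without a single gene name, 199 passed for Norrin in wild type, 133 up and 66 down.

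The first pattern weighed is the rise of endothelial genes with Norrin in wild type cells, which a larger share of mouse RNA in the mixed culture might explain. Genes lost from Fz4-/- cells in co-culture should then rise as well, if enough of their mouse signal is left. The median of 500 such genes was 0.0555 against 0.749 for pan-endothelial markers. They were picked for a fall of at least 3.85 log2 between array sets with unlike distributions, and their levels above background were not examined. A gene near the floor could not follow the share, so the comparison cannot decide. Of these 500 genes, 70 rose, 32 fell and 398 did not pass. A smaller share would lower them, and their lower quartile was -0.127 against a median of -0.533 for the genes that fell, under the same limit. A larger share large enough for such falls would raise these genes by a like amount. Their median of 0.0555 has the same limit, and the 32 that fell lie between the limits set for that count.

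The second pattern weighed is the weaker response to Norrin-expressing cells in Fz4-/- cells, which unlike or compressed values in its array set could explain. After quantile normalization over all 12 co-culture arrays 515 genes were called, 375 of the 385 among them, which argues against unlike distributions as the whole cause. The slope of the Fz4-/- on the wild type response was 0.30 (95% bootstrap interval 0.233 to 0.379, 224 genes with a mean above 8), which lies between the limits set for a damped response, and other differences between the array sets cannot be told apart from genotype. The wild type control array with an actin 3' to 5' difference of 1.62 is not the source, since 314 of the 385 genes were also called without it. For the 137 genes that fell in wild type and differed, a fall as large was taken from the Fz4-/- control level. It would end below 2.21 in 13 and below 3.16, where Lcn2 ended, in 19. The floor of the arrays therefore does not account for most of these 137. Their median control level was 6.72 in wild type and 5.95 in Fz4-/-, and an end level of a gene's own above that floor was not tested. Such a level is left open, since NF-kB and inflammatory adhesion genes ended at means of 5.44 in wild type and 5.45 in Fz4-/-. The p53 targets ended at 6.52 and 6.55. Of 213 that rose in wild type and differed, 42 lay below 3.16 in Fz4-/-, where a floor was not tested. An upper level common to both genotypes was not tested for risen genes either. Pan-endothelial markers ended at means of 7.87 in wild type and 7.965 in Fz4-/-, but cholesterol synthesis genes at 6.15 and 4.91.

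The third pattern weighed is the large difference between the lines in the single cultures, which a segment of another strain around Fzd4, fibroblasts in a line, or chance differences between lines might explain. Of 100 neighbours of Fzd4, 21 were called, against a median of 15 and an upper bound of 24 among 16041 windows of the same size. That count leaves a segment open, since 100 neighbours could not hold a large share of 2719 called genes. Fibroblast markers had a median of -0.125, with Thy1 up (4.32) and S100a4 (-2.69), Fbln1 (-2.41) and Pdgfra (-1.31) down. The 3 lower markers go with fibroblasts in the wild type line, and only Thy1, which is also on the retinal neuron list, goes the other way. The markers therefore cannot decide. The 1974 genes called alike on gelatin and Matrigel, with 3 opposite, cannot tell frizzled-4 from other differences between lines.

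Exchanging group labels gave 10 splits for each comparison of 2 groups, too few for a small p, and the real counts of 2719, 2854, 3356, 3592, 1741, 83, 9253 and 9079 were met by 0 at most in the other splits. The 4 splits that part every numbered pair, apart from the real split, also reached 0. Every other split mixes the real groups, so real differences add to its spread. Its count of 0 therefore tells little about chance. For the difference of the Matrigel response 8 of 100 splits called at least as many as the real 3, so chance cannot be excluded by this count. The highest other reached 6526 with the Fz4-/- labels exchanged whole, which adds the Matrigel responses of the genotypes instead of subtracting them. For the difference of the Norrin response 7 of 100 splits called at least as many as the real 385, so chance cannot be excluded by this count, and the highest other reached 1382. For both differences, every other split as large kept the groups of a genotype whole. Such splits still carry a real response, so both counts tell little about chance. Splits that left neither genotype whole called 0 genes in both.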

How the results depend on the processing

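Leaving out the replicate 1 arrays and averaging replicates 2 and 3 were chosen only after the result was seen.

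A 2-fold minimum left 723 genes for genotype on gelatin, 791 on Matrigel, 182 for Matrigel in wild type, 235 in Fz4-/-, 182 for Norrin in wild type, 12 in Fz4-/-, 126 for the difference of the Norrin responses, and 1248 and 1189 for genotype with control and Norrin-expressing cells. The replicate number as a block gave 4138 for genotype on gelatin, 4379 on Matrigel and 8 for the difference of the Matrigel responses, and changed no other count by more than 1.5 times. Numbers did not pair for Norrin in Fz4-/- (correlations -0.10, -0.19 and 0.006) or for genotype with control cells (-0.048, 0.066 and -0.03).

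Without replicate 1 of every group the counts were 4911 and 4857 for genotype on gelatin and Matrigel, 5088 and 5498 for Matrigel in wild type and Fz4-/-, and 61 for the difference of these responses. With replicates 2 and 3 averaged into 1 sample they were 667, 736, 574, 712 and 0 in the same order (limma, 340 at an unadjusted p below 0.05 for the last), and 691, 10 and 90 for Norrin in wild type, in Fz4-/- and their difference.

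With only genes above the median level, 1235 and 1650 genes passed for Matrigel in wild type and Fz4-/-, and 4996 and 4702 for genotype with control and Norrin-expressing cells. The difference of the Matrigel responses had 5 genes with the mean of all probe sets and 16 with all 24 arrays in 1 fit. With only the arrays compared, Norrin-expressing against control cells gave 761 genes in wild type and 162 in Fz4-/-. In Fz4-/- this comparison gave 53 after median centring and 44 with all 24 arrays.

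Gene lists past the threshold numbered 3 with the preset correlation, 0 with an estimated correlation and 9 with fry for genotype on gelatin. In that order they numbered 5, 0 and 19 on Matrigel, 4, 2 and 6 for Matrigel in wild type, 7, 2 and 13 in Fz4-/-, and 3, 0 and 0 for the difference of these responses. They numbered 14, 3 and 16 for Norrin in wild type, 12, 1 and 2 in Fz4-/-, 12, 2 and 10 for the difference of the Norrin responses, 8, 1 and 28 for genotype with control cells, and 12, 0 and 26 with Norrin-expressing cells.

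Leaving out 1 array at a time gave 1796 to 2595 genes for genotype on gelatin (1796 without wild type gelatin replicate 3, 1800 without replicate 2), 1903 to 2598 on Matrigel, 2137 to 2731 for Matrigel in wild type (2137 without wild type Matrigel replicate 2) and 2335 to 3037 in Fz4-/- (2351 and 2335 without Fz4-/- gelatin replicates 2 and 3). The difference of these responses had 2 to 5 genes (5 without Fz4-/- Matrigel replicate 1 and 5 without wild type gelatin replicate 3). Norrin-expressing against control cells gave 1266 to 2161 genes in wild type and 36 to 50 in Fz4-/- (46, 36 and 37 without control replicates 1, 2 and 3, and 50, 39 and 36 without Norrin replicates 1, 2 and 3). The difference of the Norrin responses had 232 to 562 (241, 232 and 255 without Fz4-/- control replicates 1, 2 and 3, and 242 and 248 without Fz4-/- Norrin replicates 2 and 3). Genotype in co-culture gave 7813 to 8768 and 7478 to 8613.

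Median centring split the Matrigel genes into 975 up and 2807 down in wild type and 1111 up and 3053 down in Fz4-/-. It split the genotype genes with control cells into 3571 higher and 3675 lower, and with Norrin-expressing cells into 3671 higher and 3343 lower. Quantile normalization within the fit moved the Matrigel balance the other way, to 1362 up and 1732 down in wild type and 1589 up and 1725 down in Fz4-/-. The excess of falls on Matrigel thus depends on the scaling.

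A few named genes turned direction. With only probe sets without a suffix, Laptm5 was at 0.11 on gelatin and 0.15 on Matrigel for genotype, C1qb at 0.032 for Matrigel in wild type, Igf2bp1 at -0.52 for Matrigel in Fz4-/-, Angptl4 at 0.12 for Norrin in wild type, Acta2 at 0.059 and 0.021 for genotype with control and Norrin-expressing cells, and Epcam at 0.026 in the latter. With the mean of all probe sets, Erg was at -0.029 and Angpt1 at 0.16 for Matrigel in wild type, Col1a1 at -0.0095 and Igf2bp1 at -0.0042 for Matrigel in Fz4-/-, and Vcam1 at 0.14 for Norrin in wild type. Of 17558 alternatives for 1061 named values, 16131 stayed the same, 1370 were weaker, 44 stronger and 13 reversed. Among 492 named values past the threshold for genes with over 1 probe set, 20 had another probe set past it in the opposite direction.

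The genes that rose with Norrin had a median genotype difference on Matrigel of 0.0408 among genes above the median level and 0.039 with all 24 arrays. It was -0.00169 (percentile 10.6) with the mean of all probe sets, 0.0227 (percentile 72.7) after median centring and 0.0207 (percentile 71.4) with only probe sets without a suffix. The genes that fell with Norrin had 0.000442 on gelatin and -0.00923 on Matrigel with all 24 arrays.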

Other observations

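The HoxD group and the test of genes shared after Norrin were chosen only after the result was seen.

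Homeobox genes of the HoxD cluster, which give cells a memory of their position in the body, were lower in Fz4-/- cells. Of 8 measured, 5 were lower on gelatin and 5 on Matrigel. On gelatin Hoxd8 went from 10.69 to 4.36, Hoxd9 from 8.54 to 5.11 (-3.43) and Hoxd3os1 from 8.68 to 3.35, with Hoxd1 at -0.98, Hoxd10 at -0.80 and Hoxd3 at -0.70. Of 25 other Hox genes, 1 was lower in both cultures (Hoxb4, -1.11 on gelatin and -0.89 on Matrigel) and 0 were higher. Several of these lay near the lowest values in wild type on gelatin, such as Hoxc8 (2.38), Hoxa10 (2.52) and Hoxa2 (2.53). A fall there could be missed, so the counts do not compare the clusters alike. Others had room to fall, such as Hoxa7 (6.08 in wild type) and Hoxa5 (5.99), at -0.13 and -0.09 (not past). Hoxd1 (3.69) and Hoxd10 (3.83) also started low.

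Loss of a wider region around HoxD could explain these falls. Of 10 neighbours, 2 were lower (Lnpk -0.62, Mtx2 -0.40) and 0 higher, which argues against a loss over most of these 10. Mtx2 was the nearest tested gene on its side, and only Evx2 (-0.05, not called) lay between Lnpk and the cluster. A narrower region around the cluster is therefore left open.

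With Norrin-expressing cells 27 genes fell in both genotypes, 1.84 by chance, with Cxcl5 at -4.76 and -4.47 log2. Norrin acting apart from frizzled-4 and another difference between the HEK293 lines could each give such shared falls, and the 27 genes leave both open, because no group parts Norrin from the line that makes it. The limit set for this count, more than 3 times chance, was therefore no test of frizzled-4.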
